A study of Homo sapiens with 18 samples.

How the data were processed

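RNA from 3 isogenic lines of the chronic myeloid leukaemia cell line K562 was sequenced in 18 libraries, 2 for each of 9 groups. The parental line was untreated or given interferon alpha (IFN). The VPR-D9 line was untreated or in either of the doxycycline groups D2000 and D6. The KRAB-D9 line was untreated or given IFN, doxycycline, or both. Per the labels' protocols, doxycycline at 2 µg/mL induced dCas9-VPR (an activator) or dCas9-KRAB (a repressor), and IFN was used at 1000 U/mL for 24 hours. KRAB-D9 cells received doxycycline for 24 hours before IFN, and it was continued with IFN. The sample table made here carries 2 µg/mL for D2000, from that general protocol, and leaves the dose of D6 open. What the codes D2000 and D6 stand for, whether their doses differ, and how long doxycycline was given without IFN are not given in the sources used here. No doxycycline-treated parental group was analysed here. Libraries were made with a stranded, polyA-selecting mRNA kit.

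The deposited values are raw read counts per gene, whole numbers for 41285 genes. The submitters' processing notes name cutadapt 2.10, STAR 2.7.8a, FastQC 0.11.9, featureCounts 2.0.2 and genome build GRCh38.p13, without their order. The annotation release, the strand setting of the counting and the handling of reads that map to several places are not given in the sources used here. Genes that share reads with near-identical copies or with overlapping or antisense genes are therefore uncertain; HBZ, HBG2 and RPS26 are among those named in the report.

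Libraries held 32.7 M to 63 M counts (median 52.9 M). Mitochondrially encoded genes took 3.315 to 4.963% of the counts. The group of KRAB-D9 with IFN had the shallowest library (replicate 1, 32.7 M), and the variance between its libraries was 16.1 times counting noise, against 4.47 to 6.02 in the other groups. Genes were filtered with filterByExpr by group, which left 22143. Counts were scaled by TMM, and 1 edgeR 4.0.16 quasi-likelihood model (robust) with 9 group means was fitted to all 18 libraries in R 4.3.3, with 9 residual degrees of freedom and a common biological coefficient of variation of 0.0569. Levels are TMM-scaled CPM (counts per 1e6 scaled counts), given as mean ± SD of 2 libraries. Fold changes are given on the log2 scale with a standard error (±). It was derived from the test, as the size of the fold change over the square root of its quasi-likelihood F. This error is approximate where counts are few, since fold changes use a prior count. Genes were called changed at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Dispersion was shared over the groups. Errors and p-values of comparisons that use KRAB-D9 with IFN may therefore be too small. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure only the spread between samples.

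There were 14 comparisons: treated against untreated cells within each line, D6 against D2000, differences between such effects, and the untreated lines against the parental line. The IFN effect in each line without doxycycline, the doxycycline effect in KRAB-D9 with and without IFN, and D2000 and D6 against untreated VPR-D9 cells were the main comparisons. Tests, lists, the naming rule and most other settings tried were set before the data were examined.

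There were 20 gene lists: interferon-stimulated genes, class I antigen presentation, interferon receptor signalling, cytosolic ribosomal proteins, ribosome biogenesis factors, mitochondrially encoded mRNAs, mitochondrial ribosomal proteins, nuclear oxidative phosphorylation genes, the integrated stress response, p53 targets, G1/S and G2/M cell cycle genes, cholesterol synthesis, inflammatory NF-kB targets, markers of erythroid, megakaryocyte, myeloid, lymphoid and fibroblast or epithelial cells, and 17 neighbours of SAMD9 on 7q21. SAMD9 is in no list, and SAMD9L is only among the neighbours. GDF15 is in both the stress response and the p53 list, and CYP51A1 in both the cholesterol and the 7q21 list. Lists were tested with limma 3.58.1 camera (preset inter-gene correlation 0.01), with Benjamini-Hochberg adjustment over 280 tests. The preset value can make camera too permissive, so the adjusted p with a correlation estimated from the data is given beside it or in its place. For each list, members called over all genes were counted, and members called when adjusted over the list alone. Every list is given for doxycycline in KRAB-D9, and elsewhere those called with an estimated correlation and a part of the others.

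SAMD9 and SAMD9L are named in every comparison. Otherwise the names come from the 8 genes with the largest rise and the 8 with the largest fall in a main comparison (4 and 4 in the others), and from the 3 members of each list with the smallest adjusted p. The first kind had to be called, have an approved symbol and a mean of at least 1 CPM over the compared groups, and have both libraries of one group on the same side of both libraries of the other. The text names a subset, and some genes that the rule names are not reported here. XIST and Y-linked genes were left out. Where a group had no counts, a fold is a lower bound against a floor of 3 counts per library; with 1 to 3 counts it is a ratio with a 95% counting interval. Intervals and floors cover counting error only, and fitted values of such genes depend on the prior count and are not given.

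Other settings, chosen beforehand, were DESeq2 size factors in the edgeR model, the DESeq2 1.42.0 Wald test, no filter, a filter of 1 CPM in 2 libraries, a replicate block, a model of only the compared groups, D2000 and D6 pooled as one group, leaving out each library in turn, and, for lists, camera with an estimated correlation, limma fry and camera with the replicate block. Added after the data were seen were scaling by library totals alone (for genes and lists), and leaving out replicate 1 of KRAB-D9 with IFN in comparisons that do not use it. Library totals shifted the median gene by 0.23 for D2000 and by -0.195 for D6 against D2000 (log2), relative to TMM. Every other shift between 2 groups was under 0.1. Shifts were not computed for differences between effects. The difference of the doxycycline effect between VPR-D9 (D2000) and KRAB-D9 moved as well, for SAMD9L from -0.19 to 0.01.

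The model was tested on simulated counts for all 18 libraries, drawn from each gene's mean over all groups. Genes were drawn independently, with the same spread in every group, and 200 were changed 1.5-, 2- or 4-fold in the parental IFN group. The model recovered 60, 60.9 and 73.4% of 1.5-, 2- and 4-fold changes, and 90.7, 84.8 and 100% among genes with at least 1 CPM. Of its calls, 6.72% were unchanged genes. In a simulation of the doxycycline comparison in KRAB-D9 with no change, 0 genes were called. A list raised 1.3-fold was the only list called. These draws hold no correlation between genes and no group with a wider spread, so they do not test the effect of either. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.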

Results

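SAMD9 encodes a cytoplasmic protein that restrains cell growth and is itself induced by interferon. Its RNA was followed in parental K562 cells, in cells where a dCas9 activator could be induced (VPR-D9) and in cells where a dCas9 repressor could be induced (KRAB-D9). Each group had 2 libraries. The first principal components of 9462 genes held 53, 21.4 and 11.1% of the variance.

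SAMD9 (ENSG00000205413.8, chromosome 7, 93099513 to 93118023, GRCh38) was raised by IFN, lowered by the induced repressor and raised by the induced activator. In parental cells it rose from 9.18 ± 0.18 to 161 ± 9.3 CPM with IFN, a log2 fold change of 4.13 ± 0.07 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 9.36e-28, n = 2 and 2). In KRAB-D9 cells IFN raised it from 0.557 ± 0.27 to 54.2 ± 1.1 CPM (6.55 ± 0.12). With doxycycline present, IFN left it at 0.797 ± 0.073 CPM, 67.7-fold below IFN alone (-6.08 ± 0.11, edgeR Benjamini-Hochberg adjusted p = 5.4e-26). Doxycycline without IFN lowered it to 0.0585 ± 0.083 CPM, from libraries with 0 and 6 counts (-3.23 ± 0.50, edgeR Benjamini-Hochberg adjusted p = 8.6e-06). IFN still raised SAMD9 in doxycycline-treated KRAB-D9 cells, by 3.70 ± 0.45. The sizes of both changes are uncertain. They were -2.27 and 2.74 without doxycycline replicate 1, and without replicate 2, when no counts are left, the fitted -7.94 and 8.42 depend on the prior count. The level with both treatments was not called different from that of untreated KRAB-D9 cells (0.47 ± 0.26, edgeR Benjamini-Hochberg adjusted p = 0.222). It was called when replicate 1 of the untreated group was left out (1.12, adjusted p = 0.0134), and was 0.08 without replicate 2.

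In VPR-D9 cells SAMD9 rose from 60.6 ± 1.1 CPM to 961 ± 19 CPM in D2000 and 948 ± 17 CPM in D6, 15.8- and 15.6-fold. Both levels lay above the one that IFN reached in parental cells. D6 and D2000 were not called different (-0.02 ± 0.05, edgeR Benjamini-Hochberg adjusted p = 0.821), except with library totals in place of TMM (-0.21, adjusted p = 0.00141). The untreated lines already differed. SAMD9 was 6.6-fold higher in untreated VPR-D9 (2.72 ± 0.07) and 15.9-fold lower in untreated KRAB-D9 (-3.99 ± 0.16) than in parental cells.

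SAMD9L, the neighbouring paralogue (chromosome 7, 93130056 to 93148385), responded to IFN in both lines tested. IFN raised it by 4.09 ± 0.17 in parental cells (1.34 to 23 CPM), 6.46 ± 0.21 in KRAB-D9 (0.38 to 34.5 CPM) and 5.25 ± 0.20 in KRAB-D9 with doxycycline. Its changes with either fusion were small. With doxycycline and IFN it was below IFN alone (-0.51 ± 0.13). With doxycycline alone it was not called (0.69 ± 0.35, edgeR Benjamini-Hochberg adjusted p = 0.162) unless replicate 2 of the doxycycline group was left out (1.1, adjusted p = 0.031). In D2000 it rose by 0.51 ± 0.15, a call lost without replicate 1 of the untreated VPR-D9 cells (edgeR Benjamini-Hochberg adjusted p = 0.15) or replicate 2 of D2000 (0.071). It was not called in D6 (-0.06 ± 0.16), and D6 lay below D2000 (-0.57 ± 0.16). Both treatments together raised SAMD9L by 5.95 ± 0.21 over untreated KRAB-D9 cells. Before treatment it was higher in VPR-D9 (1.61 ± 0.19) and lower in KRAB-D9 (-1.78 ± 0.3) than in parental cells.

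**Figure D1:**
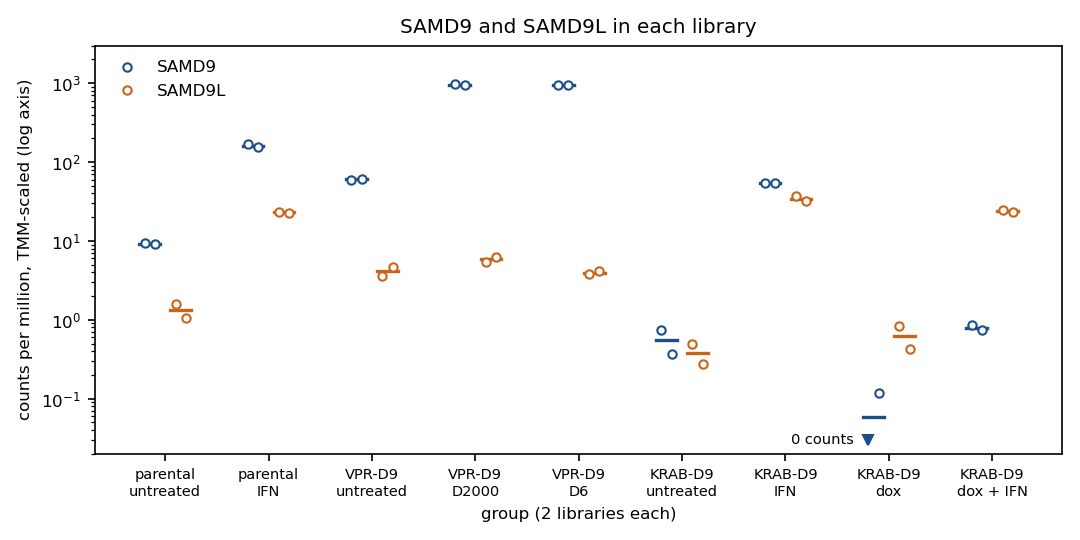
SAMD9 and SAMD9L in TMM-scaled CPM (log axis) in the 9 groups; circles are the 2 libraries of a group, bars their mean, and the triangle a library with 0 SAMD9 counts. SAMD9 ranged from 0.0585 CPM in KRAB-D9 with doxycycline to 961 CPM in D2000.

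IFN induced the antiviral programme in parental cells. MX1, a GTPase that blocks viral replication, went from 2 counts over both libraries to 757 ± 27 CPM (ratio 39800, 95% counting interval 11000 to 329000). OAS2, which senses double-stranded RNA, went from no counts to 140 ± 7.1 CPM (at least 2450-fold higher), and IFI44L was at least 1250-fold higher. The ubiquitin-like modifier ISG15 rose from 8.1 ± 0.028 to 1060 ± 23 CPM (7.03 ± 0.06, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 4.77e-45, n = 2 and 2). IFI6 rose by 10.07 ± 0.23 and IFI27 by 9.18 ± 0.08. The peptide transporter TAP1 rose by 3.33 ± 0.13 and B2M, the class I light chain, by 0.92 ± 0.04.

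IFN also changed other genes in parental cells. HMGCS1, an early enzyme of cholesterol synthesis, rose by 0.55 ± 0.04 and the sterol sensor INSIG1 by 0.34 ± 0.05. Delta-globin HBD rose by 1.12 ± 0.09 and the transferrin receptor TFRC by 0.25 ± 0.03. The mitotic genes CDC20 and CCNB1 fell by 0.31 ± 0.04 and 0.21 ± 0.04, and mitochondrially encoded MT-CO1 by 0.35 ± 0.04. The noncoding RNA DANCR fell by 0.68 ± 0.05, LONRF2 by 0.78 ± 0.09 and the p53 target ZMAT3 by 0.70 ± 0.09. IRF1 rose by 0.59 ± 0.13, a call lost without replicate 2 of the untreated cells (edgeR Benjamini-Hochberg adjusted p = 0.0871) or replicate 1 of the IFN cells (0.0814). In all, 671 genes rose and 289 fell, 161 and 17 of them over 2-fold. The 960 calls became 556, 515 and 467 without untreated replicate 1, untreated replicate 2 and IFN replicate 2.

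Of the lists, 66 of 71 interferon-stimulated genes rose in parental cells (67 adjusted over the list alone). Their median was 3.26, or 3.01 with genes at zero counts set to their bound (camera Benjamini-Hochberg adjusted p = 1.92e-11 with an estimated correlation). Class I antigen presentation genes rose in 14 of 18 cases (16 alone, median 0.88, adjusted p = 1.45e-06 with an estimated correlation). Other lists were called with the preset correlation and lost with an estimated correlation. Cholesterol synthesis genes were higher in 15 of 25 cases (18 alone, median 0.20, adjusted p = 0.188 with an estimated correlation), and erythroid markers in 11 of 37 (18 higher and 1 lower alone, 0.14, 0.112). Lower were 12 of 32 G2/M genes (18 alone, -0.12, 0.185), 5 of 13 mitochondrially encoded mRNAs (11 alone, -0.35, 0.301), 6 of 79 cytosolic ribosomal proteins (9 alone, -0.05, 0.694) and 6 of 135 ribosome biogenesis factors (7 alone, -0.04, 0.464).

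In KRAB-D9 cells IFN also raised interferon-stimulated and class I genes. MX1 went from no counts to 1030 ± 65 CPM (at least 16700-fold higher). OAS1, OAS2 and IFIT1, an RNA-binding antiviral protein, were at least 2910-, 2930- and 1420-fold higher. ISG15 rose by 7.12 ± 0.06 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.36e-44, n = 2 and 2), IFI6 by 9.70 ± 0.23, TAP1 by 5.29 ± 0.17, B2M by 1.08 ± 0.04 and IRF1 by 1.07 ± 0.13. HBD rose by 0.98 ± 0.09, the tryptophanyl-tRNA synthetase WARS1 by 0.39 ± 0.04 and HEPACAM2, near SAMD9 on 7q21, by 0.86 ± 0.12. The mitotic genes CDC20 and PLK1 fell by 0.49 ± 0.05 and 0.43 ± 0.05, and MT-ND5 by 0.48 ± 0.06. The platelet collagen receptor GP6 fell by 0.88 ± 0.15 and the neuropeptide precursor VGF by 1.11 ± 0.21.

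There were 882 genes higher and 535 lower with IFN in KRAB-D9. A model of only the compared groups gave 465 calls in all. The 1417 calls became 843 and 815 without either untreated library and 2202 without IFN replicate 2, of the pair with the widest spread. Of the parental calls, 399 of 671 were also called higher in KRAB-D9 (26.7 expected by chance) and 112 of 289 lower (6.98 expected). Only 2 were called in opposite directions. Interferon-stimulated genes rose in 68 of 71 cases (69 alone, median 3.61, camera Benjamini-Hochberg adjusted p = 9.02e-11 with an estimated correlation) and class I genes in 15 of 18 (16 alone, 1.15, 8.52e-07). The neighbours of SAMD9 on 7q21 were called higher with the preset correlation (4 of 17, 6 higher and 1 lower alone, median 0.11) but not otherwise (adjusted p = 0.067 with an estimated correlation). So were 12 of 37 erythroid markers (19 higher and 2 lower alone, 0.15, 0.105), while G2/M genes were lower in 13 of 32 cases (18 alone, -0.15, 0.184). Calls were also lost for mitochondrially encoded mRNAs (7 of 13 lower, 10 alone, median -0.39, adjusted p = 0.4 with an estimated correlation) and cytosolic ribosomal proteins (18 of 79 lower, 2 higher and 26 lower alone, -0.04, 0.698). So were those of megakaryocyte markers (3 of 17 lower, 5 alone, -0.43, 0.194) and the stress response (13 higher and 1 lower of 45, 17 and 2 alone, 0.10, 0.524).

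The IFN effect itself differed between KRAB-D9 and parental cells for 67 genes, 32 more positive and 35 more negative in KRAB-D9. SAMD9 (2.42 ± 0.19) and SAMD9L (2.36 ± 0.32) were induced more in KRAB-D9. So were TAP1 (1.96 ± 0.23), SP110 (1.01 ± 0.14) and PARP14, an ADP-ribosyltransferase (0.62 ± 0.08). The mitochondrial nucleotide kinase CMPK2 was induced less (-1.12 ± 0.08, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.33e-11), as was HMGCS1 (-0.38 ± 0.06). TRIM22 was also induced less (-1.95 ± 0.37), a call lost without parental untreated replicate 2 (edgeR Benjamini-Hochberg adjusted p = 0.123) or KRAB-D9 untreated replicate 2 (0.0559). Interferon-stimulated genes leaned to larger effects in KRAB-D9 (9 larger and 3 smaller of 71, 23 and 7 alone, median 0.20, camera Benjamini-Hochberg adjusted p = 0.00722 with an estimated correlation). Class I genes did too (1 of 18, 5 alone, 0.24, 0.00185), and cholesterol synthesis genes leaned to smaller effects (3 of 25, 15 alone, -0.22, 0.0354). The 67 calls became 992 without IFN replicate 2 of KRAB-D9 and 105 without parental IFN replicate 1. They became 26, 20, 37 and 31 without parental untreated replicate 2, parental IFN replicate 2 and KRAB-D9 untreated replicates 1 and 2.

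Doxycycline in KRAB-D9 cells lowered genes that build ribosomes. UTP20, a scaffold of the small-subunit processome, fell from 145 ± 2.4 to 86.5 ± 2.1 CPM (-0.75 ± 0.04, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.62e-16, n = 2 and 2). The processome members NOL6 and IMP4 fell by 0.75 ± 0.05 and 0.66 ± 0.04. PHGDH, the first step of serine synthesis, rose from 12.4 ± 0.75 to 38.6 ± 5.3 CPM (1.64 ± 0.09), the cystine transporter SLC7A11 by 1.14 ± 0.09, the stress regulator ATF4 by 0.49 ± 0.04 and CHAC1, which degrades glutathione, by 2.09 ± 0.40. The sterol enzymes HMGCS1 and LSS rose by 0.67 ± 0.04 and 0.67 ± 0.05. Erythroid genes rose as well, among them EPB42, a red-cell membrane protein (1.96 ± 0.16), the haem enzyme ALAS2 (0.70 ± 0.04) and the iron carrier SLC25A37 (0.69 ± 0.04).

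Further single genes changed with doxycycline in KRAB-D9. GP6 fell by 2.68 ± 0.17, the T-cell receptor chain CD3D by 2.46 ± 0.25, S100P by 3.17 ± 0.40 and VGF by 2.34 ± 0.22. Fibronectin FN1 fell by 1.18 ± 0.10, lysozyme LYZ by 0.87 ± 0.08, the myeloid receptor CD33 by 0.81 ± 0.07 and the keratins KRT8 and KRT18 by 0.53 ± 0.05 and 0.43 ± 0.04. LOXL4, a collagen cross-linking enzyme, rose by 3.29 ± 0.43, PCSK1N by 2.38 ± 0.39 and TP53INP1 by 1.32 ± 0.12. Interferon-stimulated genes were split, with STAT2 (0.50 ± 0.05) and UBE2L6 (0.81 ± 0.09) higher and IFITM2 (-0.93 ± 0.05) lower. The cytokine brake SOCS1, of the interferon receptor signalling list, was lower (-1.03 ± 0.18). The chaperone CALR fell by 0.59 ± 0.04, the nucleotide reductase RRM2 by 0.29 ± 0.04 and the mitochondrial ribosomal gene MRPL1 by 0.54 ± 0.06. There were 2654 genes higher and 2815 lower, 354 and 288 of them over 2-fold (48.5% higher, or 57.2% with library totals, 3162 and 2368).

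Ribosome biogenesis factors fell as a group in KRAB-D9 with doxycycline (114 of 135, 121 alone, median -0.36, camera Benjamini-Hochberg adjusted p = 0.000457 with an estimated correlation). Erythroid markers rose (25 higher and 2 lower of 37, the same alone, 0.40, 0.00142). Fibroblast or epithelial markers fell (7 of 9, the same alone, -1.17, or -0.59 with genes at zero counts set to their bound, 0.00381). Other calls were lost with an estimated correlation. They were cholesterol synthesis (18 higher and 1 lower of 25, 19 and 1 alone, 0.29, adjusted p = 0.0525 with an estimated correlation), the stress response (25 and 2 of 45, 26 and 4 alone, 0.20, 0.065) and mitochondrially encoded mRNAs (6 of 13 higher, 7 alone, 0.24, 0.584) on the higher side. On the lower side were mitochondrial ribosomal proteins (2 higher and 36 lower of 80, 3 and 41 alone, -0.15, 0.0916), class I genes (7 of 18 lower, the same alone, -0.19, 0.0916) and G1/S genes (1 and 13 of 29, 1 and 15 alone, -0.12, 0.196). So were myeloid markers (4 of 15, 7 alone, -0.71, 0.0524) and NF-kB targets (4 of 20, the same alone, -0.26, 0.184).

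The remaining lists were not called in KRAB-D9 with doxycycline. Interferon-stimulated genes had 20 members higher and 11 lower (22 and 11 alone, median 0.11), and interferon receptor signalling 3 and 4 of 15 (3 and 5 alone, -0.06). Nuclear oxidative phosphorylation had 4 and 16 of 71 (7 and 16 alone, -0.04) and G2/M genes 11 and 1 of 32 (11 and 3 alone, 0.05). Megakaryocyte markers had 4 and 6 of 17 (the same alone, -0.12), lymphoid markers 2 of 14 lower (the same alone, -0.30) and 7q21 neighbours 4 and 2 of 17 (5 and 2 alone, 0.15). Cytosolic ribosomal proteins, 8 higher and 7 lower (8 and 6 alone, median 0.03), turned to 7 and 9 with DESeq2 size factors. For p53 targets (6 and 6 of 22, the same alone) the median was -0.01 and the mean 0.04, and the median turned to 0.03 with library totals.

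With IFN present, doxycycline moved many of the same genes. Of those higher with doxycycline alone, 1581 of 2654 were also higher with IFN (276 expected by chance), and of those lower, 1949 of 2815 (334 expected). UTP20 fell by 0.70 ± 0.04, NOL6 by 0.83 ± 0.05 and the snoRNP protein NOP56 by 0.54 ± 0.04. HMGCS1 rose by 0.83 ± 0.04 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 9.19e-18, n = 2 and 2), LSS by 0.85 ± 0.05, PHGDH by 1.33 ± 0.09, ATF4 by 0.53 ± 0.04 and SLC7A11 by 0.87 ± 0.08. The blood-group gene RHD (1.03 ± 0.08), SLC25A37 (0.58 ± 0.04), LOXL4 (3.85 ± 0.44), TP53INP1 (1.39 ± 0.13) and the cyclin CCNG1 (0.39 ± 0.05) rose too. S100P fell by 2.63 ± 0.38, the growth factor IGF1 by 2.36 ± 0.25, FN1 by 1.26 ± 0.10 and MRPS35 by 0.40 ± 0.05.

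Some interferon-stimulated and class I genes were lower with IFN and doxycycline than with IFN alone. IFI44L fell from 66.3 to 32 CPM (-1.05 ± 0.09), IFIT3 by 0.74 ± 0.08 and IFITM2 by 0.94 ± 0.05. Among class I genes, B2M fell by 0.36 ± 0.04, the proteasome activator PSME2 by 0.44 ± 0.05 and CALR by 0.68 ± 0.03. Doxycycline without IFN changed IFITM2 and CALR by similar amounts (-0.93 and -0.59). As groups, interferon-stimulated genes fell (7 higher and 23 lower of 71, 9 and 24 alone, median -0.17, camera Benjamini-Hochberg adjusted p = 0.0354 with an estimated correlation), and so did class I genes (7 of 18, the same alone, -0.30, 0.0106). Ribosome biogenesis factors (115 of 135, 119 alone, -0.35, 0.000469) and fibroblast or epithelial markers (6 of 9, the same alone, -0.35, 0.0114) fell. Cholesterol synthesis (21 higher and 1 lower of 25, 22 and 1 alone, 0.42, 0.0102), erythroid markers (20 and 3 of 37, 21 and 5 alone, 0.27, 0.00681) and p53 targets (9 and 2 of 22, 9 and 3 alone, 0.19, 0.0462) rose. Mitochondrial ribosomal proteins (40 of 80 lower, 47 alone, -0.18) and the stress response (22 and 4 of 45, 24 and 4 alone, 0.21) lost their calls (adjusted p = 0.0516 and 0.0718 with an estimated correlation). Doxycycline with IFN changed 4929 genes, 2302 higher and 2627 lower (46.7% higher, or 61.4% with library totals, 3109 and 1955). A model of only the compared groups, which hold the pair with the widest spread, gave 3270 calls in all.

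IFN in doxycycline-treated KRAB-D9 cells still raised MX1 from no counts to 782 CPM (at least 13200-fold). ISG15 rose by 6.87 ± 0.06 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 4.16e-44, n = 2 and 2), IFI27 by 8.92 ± 0.08 and TAP1 by 5.04 ± 0.16. The ribosomal protein RNAs RPS3A and RPL5 fell by 0.32 ± 0.04 and 0.31 ± 0.04, and CDC20 by 0.39 ± 0.05. The replication genes RRM2 and MCM3 rose by 0.34 ± 0.04 and 0.28 ± 0.04. IGF1 fell by 1.11 ± 0.26, though it was not called without replicate 2 of the doxycycline cells (adjusted p = 0.0547) or of the cells with both treatments (0.157). Interferon-stimulated genes rose in 67 of 71 cases (69 alone, median 3.61, camera Benjamini-Hochberg adjusted p = 1.92e-11 with an estimated correlation) and class I genes in 15 of 18 (15 alone, 1.15, 8.52e-07). Cytosolic ribosomal proteins were lower in 45 of 79 cases (62 alone, -0.18), a call lost otherwise (adjusted p = 0.188 with an estimated correlation). There were 691 genes higher and 391 lower. The 1082 calls became 591, 649, 644 and 650 without doxycycline replicates 1 and 2 and replicates 1 and 2 of both treatments.

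The interaction of IFN and doxycycline was called for 35 genes, 14 positive and 21 negative (1987 at an unadjusted p under 0.05). UBE2L6, an ISG15-conjugating enzyme, was induced less with doxycycline (-0.82 ± 0.10, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 8.24e-06). So was OAS3 (-0.75 ± 0.11), and the interaction was negative for the transglutaminase TGM2 (-0.62 ± 0.07). Starting levels differed, since doxycycline alone raised UBE2L6 by 0.81. OAS3 stood at 7.04 CPM with doxycycline alone against 4.52 CPM in untreated cells. With IFN it reached 793 CPM under doxycycline and 847 CPM without. SAMD9 itself was not called (-2.85 ± 0.87, edgeR Benjamini-Hochberg adjusted p = 0.253), except with the DESeq2 Wald test (-2.80, adjusted p = 0.00517) and without doxycycline replicate 1 (-3.81, adjusted p = 0.0189). Its sign turned without replicate 2 (1.86, adjusted p = 0.881). SAMD9L was not called (-1.20 ± 0.37, edgeR Benjamini-Hochberg adjusted p = 0.249), except without IFN replicate 2 (-1.31, adjusted p = 0.0236). Interferon-stimulated genes leaned to smaller IFN effects under doxycycline (1 positive and 5 negative of 71, 4 and 16 alone, median -0.26, camera Benjamini-Hochberg adjusted p = 0.00788 with an estimated correlation). Over the 59 members with more than 3 counts in every group the median was -0.24. The list's median IFN effect was 3.61 both with and without doxycycline, and doxycycline alone had 20 members higher and 11 lower. G1/S genes leaned to larger IFN effects (0 called over all genes, 11 of 29 alone, 0.14, 0.0185). The difference was also positive for p53 targets (0 of 22, 0 alone, 0.08, 0.0339). Their median IFN effect was -0.07 without doxycycline and 0.05 with it, so this lean is not to larger effects. Erythroid markers leaned to smaller IFN effects (0 of 37, 4 alone, -0.13, 0.0339). The 35 calls became 769 without IFN replicate 2. They became 19, 18, 21, 21 and 17 without untreated replicates 1 and 2, doxycycline replicates 1 and 2, and replicate 2 of both treatments.

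Against untreated KRAB-D9 cells, both treatments together joined these patterns. MX1 was at least 12700-fold higher, ISG15 rose by 6.72 ± 0.06 and PHGDH by 1.46 ± 0.09. HMGCS1 doubled from 262 ± 5.2 to 525 ± 20 CPM (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 5.87e-21, n = 2 and 2). UTP20 and NOL6 fell by 0.75 ± 0.04 and 0.75 ± 0.05, VGF by 2.75 ± 0.23 and the leukocyte gene LST1 by 3.27 ± 0.44. Genes higher and lower numbered 2762 and 2773 (49.9% higher, or 60.6% with library totals, 3388 and 2204). Interferon-stimulated genes (66 higher and 1 lower of 71, 67 and 1 alone, median 3.56, camera Benjamini-Hochberg adjusted p = 2.65e-09 with an estimated correlation), class I genes (14 and 1 of 18, the same alone, 0.99, 3.76e-05) and erythroid markers (27 and 1 of 37, the same alone, 0.42, 0.00381) rose. Ribosome biogenesis factors fell (115 of 135, 121 alone, -0.34, 0.00308).

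In VPR-D9 cells of group D2000, ribosome biogenesis factors fell together with erythroid and G1/S genes. The nucleolar helicase DDX21 fell from 1000 ± 8.7 to 373 ± 2.1 CPM (-1.43 ± 0.04, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 7.52e-29, n = 2 and 2), and NOLC1, a nucleolar chaperone, by 1.40 ± 0.04. TFRC fell by 1.57 ± 0.04, ALAS2 by 1.52 ± 0.05, the erythroid factor NFE2 by 1.45 ± 0.04 and embryonic globin HBZ by 3.09 ± 0.18. The replicative helicase genes MCM4 and MCM7 fell by 1.09 ± 0.04 and 1.04 ± 0.04, RRM2 by 0.92 ± 0.04 and the cyclins CCNA2 and CCNB1 by 1.12 ± 0.04 and 0.80 ± 0.04. CDK6, near SAMD9, fell by 0.93 ± 0.04. The myeloid integrin ITGAM rose from 7.87 ± 0.65 to 192 ± 1.1 CPM (4.60 ± 0.08), collagen COL1A1 by 3.33 ± 0.15 and DHX58, a regulator of viral RNA sensing, by 3.13 ± 0.15.

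Some genes of D2000 were switched on from near silence. DPEP1, a kidney dipeptidase, went from no counts to 46 ± 3 CPM (at least 944-fold) and DMKN was at least 183-fold higher. RNF223 went from 2 counts to 151 ± 8.3 CPM (ratio 9280, 95% counting interval 2570 to 76600). STAR, a mitochondrial cholesterol carrier, fell from 164 to 9.27 CPM (-4.14 ± 0.06), CD24 by 3.02 ± 0.06, TCN1 by 3.97 ± 0.35, IGF1 by 3.71 ± 0.27 and CALB1 by 3.53 ± 0.11. The proline enzyme PYCR1 fell by 1.57 ± 0.05, the folate enzyme MTHFD1L by 1.67 ± 0.06 and the arginine transporter SLC7A1 by 1.42 ± 0.06. MRPL3 (-1.18 ± 0.05), RPS26 (-0.90 ± 0.04), RPSA (-0.54 ± 0.03), ATP5F1B (-0.66 ± 0.03), CYC1 (-0.82 ± 0.04) and AEN (-1.56 ± 0.06) fell. BTG2 (1.67 ± 0.07), TM7SF2 (1.83 ± 0.09), IFI27 (2.05 ± 0.10) and SOCS3 (0.75 ± 0.10) rose. There were 4853 genes higher and 5348 lower (2120 and 784 over 2-fold). The higher share, 47.6%, was 68.6% with library totals (7195 and 3286).

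As groups in D2000, ribosome biogenesis factors fell (129 of 135, 130 alone, median -0.92, camera Benjamini-Hochberg adjusted p = 8.59e-05 with an estimated correlation). So did mitochondrial ribosomal proteins (1 higher and 75 lower of 80, the same alone, -0.63, or -0.40 with library totals, 0.00788), G1/S genes (1 and 28 of 29, the same alone, -0.66, or -0.43 with library totals, 0.00402) and erythroid markers (29 of 37, the same alone, -0.88, 0.00142). Interferon-stimulated genes (41 higher and 8 lower of 71, 41 and 9 alone, 0.51, 0.014) and myeloid markers (4 and 1 of 15, the same alone, 0.76, 0.0403) rose. Cytosolic ribosomal proteins were lower in 74 of 79 cases (the same alone, median -0.32, or -0.09 with library totals), a call lost otherwise (adjusted p = 0.284 with an estimated correlation). Nuclear oxidative phosphorylation (1 and 57 of 71, the same alone, -0.40, 0.101), the stress response (10 and 26 of 45, the same alone, -0.24, 0.194) and G2/M genes (1 and 24 of 32, the same alone, -0.30, 0.119) lost theirs too. With library totals the medians of these 3 lists were -0.17 (6 and 33), -0.01 (16 and 21) and -0.07 (5 and 15). Not called were cholesterol synthesis (4 and 16 of 25, the same alone, -0.29, or -0.06 with library totals), class I genes (6 and 3 of 18, 7 and 3 alone, 0.31, or 0.54) and p53 targets (12 and 5 of 22, 12 and 6 alone, 0.26, or 0.49). Mitochondrially encoded mRNAs (2 of 13 lower, the same alone, -0.05) turned to 5 higher with library totals (0.18).

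D6, with about the same SAMD9 level, changed fewer genes, 707 higher and 754 lower (209 and 19 over 2-fold). COL1A1 rose by 3.37 ± 0.15, to 31.2 ± 0.34 CPM (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.65e-19, n = 2 and 2), ITGAM by 2.87 ± 0.08 and the G-protein subunit GNG8 by 6.26 ± 0.29. RNF223 (ratio 3230, 95% counting interval 894 to 26700) and DPEP1 (at least 150-fold) were switched on. The vitamin B12 carrier TCN1 fell by 1.56 ± 0.31, MS4A3 by 1.08 ± 0.18 and fetal globin HBG2 by 0.55 ± 0.08. Falls were slight for CCNA2 (-0.24 ± 0.04), MCM7 (-0.21 ± 0.04), RRM2 (-0.20 ± 0.04), CDK6 (-0.22 ± 0.04) and the biogenesis factor EBNA1BP2 (-0.24 ± 0.04). MRPL47 (0.50 ± 0.05), TM7SF2 (0.61 ± 0.09) and the ubiquitin ligase DTX3L (0.34 ± 0.06) rose. The ribosomal RNA methyltransferase FBL fell by 0.19 ± 0.04, but was not called without untreated replicate 1 (adjusted p = 0.0568). The 1461 calls became 752, 784, 762 and 853 without untreated replicates 1 and 2 and D6 replicates 1 and 2. Their higher share, 48.4%, was 69% with library totals (878 and 394).

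As groups in D6, G1/S genes fell (11 of 29, 18 alone, median -0.13, camera Benjamini-Hochberg adjusted p = 0.0469 with an estimated correlation), as did erythroid markers (14 of 37, 1 higher and 23 lower alone, -0.15, 0.00948). Myeloid markers were higher, with ITGAM the only member called (1 of 15, the same alone, 0.09, 0.0109). Ribosome biogenesis factors were lower in 14 of 135 cases (24 alone, -0.07), or 4 with library totals, and lost their call (adjusted p = 0.112 with an estimated correlation). Interferon-stimulated genes (12 higher and 3 lower of 71, 15 and 5 alone, 0.07, 0.133) and G2/M genes (8 of 32 lower, 13 alone, -0.10, 0.183) lost theirs. Cytosolic ribosomal proteins (3 of 79 lower, 1 alone, -0.03, 0.717) did too, and turned to 1 higher with library totals.

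Set against D2000 directly, D6 cells held more STAR (3.37 ± 0.06, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.12e-33, n = 2 and 2), CD24 (2.78 ± 0.06), TFRC (1.43 ± 0.04) and MCM4 (0.92 ± 0.04). They held more RNA of the biogenesis factors MRTO4 (1.42 ± 0.04), NOLC1 (1.37 ± 0.04) and DDX21 (1.33 ± 0.04). LOXL4 (-5.36 ± 0.38), FBLN2 (-3.90 ± 0.34), DHX58 (-2.56 ± 0.15), IFI27 (-1.94 ± 0.10) and ITGAM (-1.74 ± 0.07) were lower. There were 4797 genes higher and 4152 lower in D6 (53.6% higher, or 31.2% with library totals, 2945 and 6481). Biogenesis factors were higher (128 of 135, 130 alone, median 0.84, or 0.64 with library totals, camera Benjamini-Hochberg adjusted p = 4.31e-05 with an estimated correlation). Interferon-stimulated genes were lower (9 higher and 39 lower of 71, 11 and 39 alone, -0.46, 0.0184). Mitochondrial ribosomal proteins (74 of 80, 75 alone, 0.56, 0.00531), G1/S genes (28 and 1 of 29, the same alone, 0.54, 0.00505) and erythroid markers (23 and 2 of 37, the same alone, 0.62, 0.00235) were higher.

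Of 1383 genes called in both D6 and D2000, 1349 moved the same way. Of those higher in D6, 650 of 707 were called higher in D2000 (155 expected if independent), and of those lower, 699 of 754 (182 expected). Both comparisons use the same untreated libraries, which favours overlap and moves in the same direction. The expected numbers are therefore too low, by an amount that was not estimated. In 93.5% of the shared genes the change was larger in D2000, with a median ratio of D6 to D2000 of 0.4. The fold changes correlated at r = 0.71 over 13551 genes, against 0.49 in 10 simulations where only the shared untreated libraries linked them (covariance 0.243 against 0.012).

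**Figure D2:**
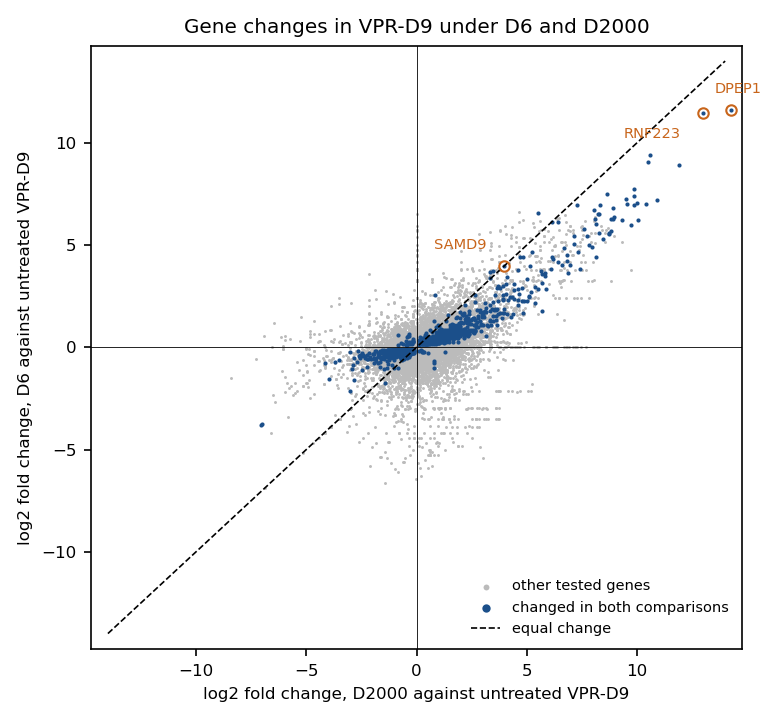
Log2 fold changes of all tested genes against untreated VPR-D9 cells, D6 against D2000; blue points were called in both (1383), the dashed line marks equal change, and fitted values of genes with no counts in a group depend on the prior count. Most called genes lie nearer 0 in D6 (93.5%).

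The doxycycline effect differed between VPR-D9 (D2000) and KRAB-D9 for 6930 genes, 2694 more positive and 4236 more negative in VPR-D9 (38.9% more positive, or 63.2% with library totals, 4208 and 2450). SAMD9 differed by 7.22 ± 0.46 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.91e-13), or a fitted 11.92 without doxycycline replicate 2 of KRAB-D9. SAMD9L was not called (-0.19 ± 0.38, edgeR Benjamini-Hochberg adjusted p = 0.786). Effects were more negative in VPR-D9 for the erythroid genes ALAS2 (-2.22 ± 0.06), TFRC (-1.71 ± 0.05) and red-cell pyruvate kinase PKLR (-3.85 ± 0.09). They were also more negative for ATF4 (-1.18 ± 0.06), PYCR1 (-1.61 ± 0.07), MTHFD1L (-1.72 ± 0.08), HMGCS1 (-1.53 ± 0.06), DDX21 (-0.93 ± 0.05) and MCM4 (-0.86 ± 0.05). ITGAM (4.82 ± 0.23) and COL1A1 (4.59 ± 0.25) had more positive ones.

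Among lists, erythroid markers had more negative effects in VPR-D9 (32 of 37, the same alone, median -1.42, camera Benjamini-Hochberg adjusted p = 3.76e-05 with an estimated correlation). So had biogenesis factors (121 of 135, 1 positive and 125 negative alone, -0.52, 0.00178), G1/S genes (26 of 29, 27 alone, -0.60, 0.00681) and G2/M genes (24 of 32, 25 alone, -0.43, 0.0469). Mitochondrial ribosomal proteins (1 and 65 of 80, the same alone, -0.47, 0.0256) had too. Stress response genes followed (4 and 30 of 45, 4 and 32 alone, -0.48, 0.0205), and myeloid markers went the other way (8 of 15, 9 alone, 1.61, 0.0173). These medians rest on TMM. They are not given here with library totals, which moved the share of more positive effects, as given above. Of genes raised by doxycycline in KRAB-D9, 1407 of 2654 were also higher in D2000 (582 expected by chance) and 451 lower. Of those it lowered, 1991 of 2815 were also lower (680 expected) and 330 higher.

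**Figure D3:**
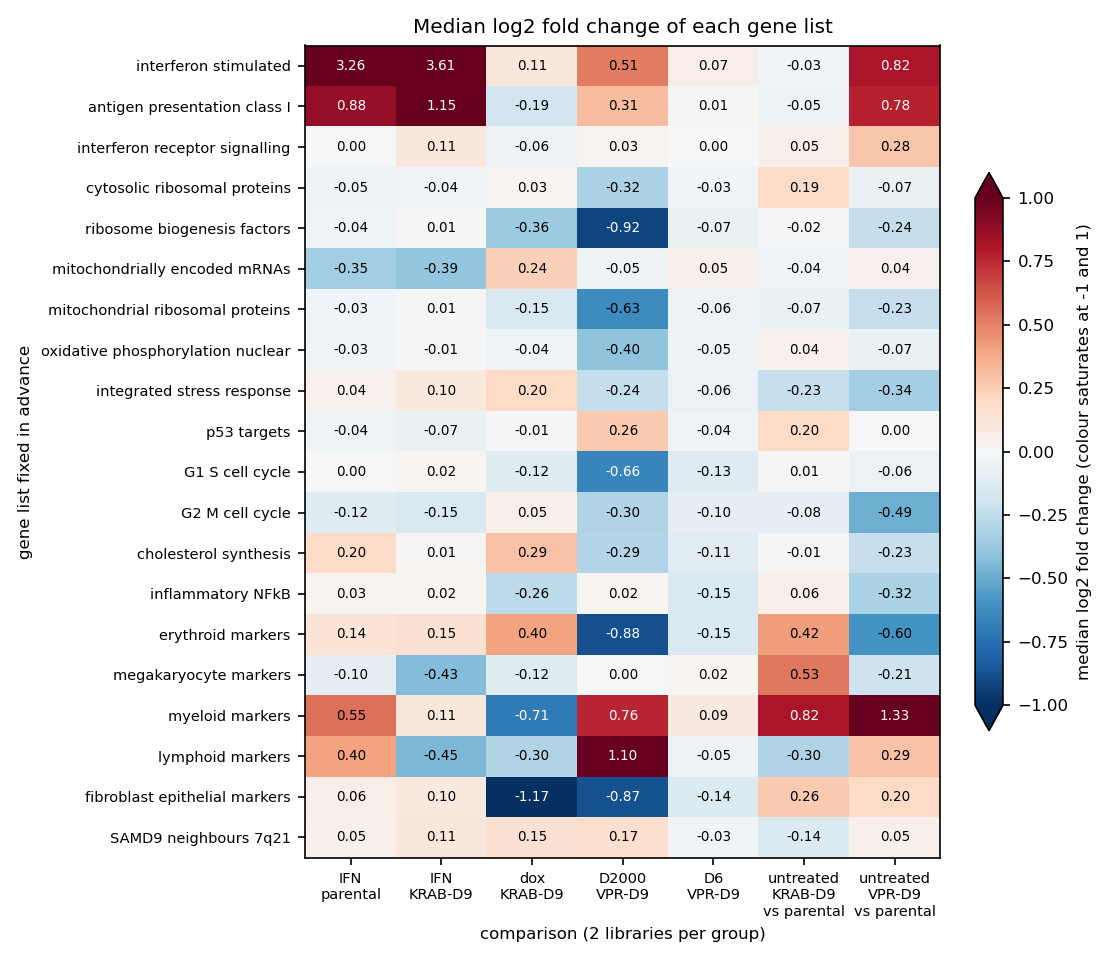
Median log2 fold change of the 20 gene lists (vertical) in 7 comparisons (horizontal), with colour saturating at -1 and 1. Biogenesis factors are lower in D2000 (-0.92) and KRAB-D9 with doxycycline (-0.36) and erythroid markers move apart (-0.88 and 0.40), while with library totals the sign flips for mitochondrially encoded mRNAs in D2000 (0.18), p53 targets in KRAB-D9 with doxycycline (0.03), 7q21 neighbours in D6 (0.01) and G1/S genes in untreated VPR-D9 (0.01).

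The untreated lines differed from the parental line before any treatment. Untreated VPR-D9 cells had more interferon-stimulated RNA. ISG15 was higher by 1.99 ± 0.06 (8.1 ± 0.028 to 32.1 ± 1.4 CPM, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 5.56e-26, n = 2 and 2), UBE2L6 by 2.58 ± 0.08, CMPK2 by 1.77 ± 0.06 and the proteasome activator PSME1 by 0.89 ± 0.05. Myeloid CD33 (1.77 ± 0.07), IGFL2 (6.95 ± 0.41) and haem oxygenase HMOX1 (at least 43.1-fold) were higher. MPDZ (at least 449-fold), LTBP1 (-4.52 ± 0.09), the mitotic gene DLGAP5 (-1.05 ± 0.05), ATF4 (-0.58 ± 0.04) and nucleolin NCL (-0.50 ± 0.04) were lower. In all, 4103 genes were higher and 4041 lower (50.4% higher, or 60.2% with library totals, 4968 and 3282).

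As groups in untreated VPR-D9, interferon-stimulated genes (43 higher and 6 lower of 71, 44 and 6 alone, median 0.82, camera Benjamini-Hochberg adjusted p = 0.000457 with an estimated correlation) and class I genes (13 and 1 of 18, the same alone, 0.78, 0.00294) were higher. Myeloid markers were higher too (7 of 15, the same alone, 1.33, 0.0196). Biogenesis factors (3 higher and 96 lower of 135, 5 and 101 alone, -0.24, 0.0469), G2/M genes (29 of 32, 30 alone, -0.49, 0.00948) and erythroid markers (6 and 24 of 37, 6 and 25 alone, -0.60, 0.00389) were lower. So were megakaryocyte markers (2 and 6 of 17, the same alone, -0.21, 0.021).

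Untreated KRAB-D9 cells held more RNA of erythroid genes. ALAS2 was 6.54-fold higher than in parental cells (2.71 ± 0.05, to 245 CPM) and the glycophorin GYPE higher by 1.34 ± 0.05. The p53 targets BTG2, GDF15 and CDKN1A were higher by 1.91 ± 0.07, 2.11 ± 0.08 and 1.22 ± 0.15. Neurotensin NTS (4.81 ± 0.26), CMPK2 (1.66 ± 0.07, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 3.04e-22, n = 2 and 2) and RPL7A (0.33 ± 0.03) were higher. TAP1 (-2.45 ± 0.20), the serine enzyme PSAT1 (-1.68 ± 0.07), S100A6 (at least 88.6-fold) and the chemokine CXCL11 (at least 48.8-fold) were lower. There were 3144 genes higher and 3162 lower. Erythroid markers (28 higher and 1 lower of 37, 29 and 2 alone, median 0.42, camera Benjamini-Hochberg adjusted p = 0.000469 with an estimated correlation) and p53 targets (12 and 2 of 22, 13 and 2 alone, 0.20, 0.00531) were higher. Megakaryocyte markers lost their call (7 and 2 of 17, 8 and 3 alone, 0.53, adjusted p = 0.188 with an estimated correlation). Interferon-stimulated genes were split (10 and 20 of 71, 14 and 20 alone, -0.03).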

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

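The tests of SAMD9 RNA and of a common exposure below were chosen only after the result was seen, and so was the use of library totals in the tests of scaling, while the DESeq2 size factors there were set beforehand.

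The effect of a treatment differed between lines, or with another treatment, in 3 of the comparisons, each by a test of the difference itself. IFN acted differently in KRAB-D9 and parental cells on 67 genes. SAMD9 (2.42), SAMD9L (2.36), TAP1 (1.96), SP110 (1.01) and PARP14 (0.62) were induced more in KRAB-D9, and CMPK2 (-1.12), HMGCS1 (-0.38) and TRIM22 (-1.95) less. SAMD9 and TAP1 started lower in untreated KRAB-D9 cells (0.557 and 0.81 CPM, against 9.18 and 4.49) and ended lower with IFN (54.2 and 32 CPM, against 161 and 45.2). CMPK2 started higher (44.8 against 14.2 CPM).

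Within KRAB-D9, the IFN effect differed with and without doxycycline for 35 genes. UBE2L6 (-0.82), OAS3 (-0.75), CMPK2 (-0.42), TGM2 (-0.62), DHRS2 (-0.74) and the ribosomal gene RPS18 (-0.25) had negative interactions, and TNS2 (1.22), GP6 (1.14) and IFI16 (0.91) positive ones. The calls of UBE2L6, OAS3 and TGM2 held without each library in turn. TNS2, DHRS2 and RPS18 also lost their calls under a setting not listed next, with a higher adjusted p than the values given there. CMPK2 was lost without doxycycline replicate 1 (adjusted p = 0.123) or replicate 2 of both treatments (0.0922). TNS2 was lost without these libraries (0.121 and 0.12) and without untreated replicate 2 (0.0718). GP6 was lost without them (0.176 and 0.401) and without untreated replicates 1 and 2 (0.0668 and 0.083). IFI16 was lost without untreated replicate 1 (0.105) or doxycycline replicate 2 (0.185), and DHRS2 without untreated, doxycycline or combined replicate 1 (0.115, 0.101 and 0.136). RPS18, a gene with near-identical copies, was lost without untreated replicate 2, IFN replicate 1, doxycycline replicate 1 and combined replicate 2 (0.158, 0.0659, 0.143 and 0.194).

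Between VPR-D9 (D2000) and KRAB-D9, the doxycycline effect differed for 6930 genes, SAMD9 among them (7.22). Erythroid ALAS2 (-2.22), TFRC (-1.71) and PKLR (-3.85), the biogenesis factor DDX21 (-0.93) and the stress regulator ATF4 (-1.18) had more negative effects in VPR-D9. So had the metabolic genes MTHFD1L (-1.72), PYCR1 (-1.61) and HMGCS1 (-1.53) and the replication gene MCM4 (-0.86). ITGAM (4.82) and COL1A1 (4.59) had more positive ones. The lines carry different fusions and their untreated cells differ, so the origin of these differences was not separated.

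The change of 5469 genes by doxycycline in KRAB-D9 was weighed first. If SAMD9 RNA moved these genes one way as it fell and the other way as it rose, genes called in both lines would move in opposite directions in D2000. Yet 81.3% of 4178 moved the same way (95% interval 80.1 to 82.5%, with genes taken as independent). SAMD9 fell from 0.557 to 0.0585 CPM in KRAB-D9 but rose from 60.6 to 961 CPM in D2000. The ranges do not meet, and an exposure shared by both lines could hide opposite moves, so this share does not exclude a part of SAMD9. The number of calls held under other scalings (5432 to 5530). That count cannot test their direction, since calls lost on one side can be gained on the other. The share of higher calls did move with library totals, as given above. An exposure common to both lines, to doxycycline or to any dCas9 fusion, may contribute, and would also make genes move the same way. The correlation with D2000 over 5468 called genes was low (r = 0.233, 0.166 to 0.291). No doxycycline-treated cells without a fusion were analysed here, so such an exposure cannot be told apart from effects of the line. A SAMD9-dependent share of the genes, which the test over all of them would miss, stays open.

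The difference of 8949 genes between D2000 and D6 was weighed next. A different level of SAMD9 RNA at harvest does not account for it, since the levels were close (-0.02, -0.12 to 0.09 at 2 standard errors, or -0.21 with library totals). Scaling changed the count little (8952 to 9426). The count cannot test direction, and the share of higher calls moved with library totals, as given above. An exposure that acts alike on KRAB-D9 cells would give a slope near 1 for 1907 genes over 2-fold apart, and the slope was 0.139 (0.107 to 0.171). A different time, dose or way of exposure behind the codes, acting on VPR-D9 cells alone, could explain the difference and was not tested.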

How the results depend on the processing

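The settings with library totals, and those without replicate 1 of KRAB-D9 with IFN in comparisons that do not use it, were chosen only after the result was seen. Among the named genes no called value turned its sign, while 8 values of SAMD9 and SAMD9L that were not called did (4 and 4). Signs of genes not named were not compared, and some list medians near 0 and shares of higher calls turned with the scaling, as given beside them. Of 177 counts of changed genes 141 stayed within 1.5 times, of 177 values of SAMD9 169 kept their sign and their side of the threshold (4 became stronger), and of 2999 values of other named genes 2927 did (66 became weaker and 2 stronger).

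A model of only the compared groups has fewer libraries. It gave 465 calls for IFN in KRAB-D9 and 3270 for doxycycline with IFN. It gave 14 for the interaction and 22 for the difference in IFN effect between lines. All of these comparisons use the KRAB-D9 libraries with IFN, whose variance was 16.1 times counting noise. D6, which does not use them, had 2327. The DESeq2 Wald test gave 85 for the interaction and 127 for the difference in IFN effect between lines, and no filter gave 74 and 133. The cause was not tested. D2000 and D6 pooled as one group gave 867 in place of 10201, since their own difference became spread within the group, and 32 named genes of D2000 lost their call there.

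Leaving out each library in turn leaves a group with 1 library, assumed to vary like the others. Counts then ran from 467 to 1359 for IFN in parental cells, 815 to 2202 in KRAB-D9, 591 to 1559 in KRAB-D9 with doxycycline, 752 to 2129 for D6, 17 to 769 for the interaction and 20 to 992 for the difference in IFN effect. The lowest ends came from parental IFN replicate 2, KRAB-D9 untreated replicate 2, doxycycline replicate 1, VPR-D9 untreated replicate 1, replicate 2 of both treatments and parental IFN replicate 2. The highest ends came from replicate 1 of KRAB-D9 with IFN (1359, 1559 and 2129) or its replicate 2 (2202, 769 and 992), the pair with the widest spread. Either removal takes that spread out of the dispersion estimate.

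SAMD9 was called under further settings in 3 comparisons. Its interaction was -2.80 with DESeq2 (adjusted p = 0.00517) and ran from -3.81 to 1.86 as libraries were left out, the highest without doxycycline replicate 2, the only doxycycline library with SAMD9 counts. Both treatments against none ran from 0.08 to 1.12 (untreated replicates 2 and 1). D6 against D2000 was -0.21 with library totals (adjusted p = 0.00141), 0 with only the compared groups and -0.05 to 0 as libraries were left out. SAMD9L in D6 ran from -0.23 to 0.13 (untreated replicates 1 and 2). Its difference between VPR-D9 and KRAB-D9 was 0.01 with library totals and ran from -0.69 to 0.36 (KRAB-D9 untreated and doxycycline replicate 1). The cause was not tested. In the other comparisons SAMD9 kept its call under every setting.

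Lists depended on the assumed correlation between genes. Of 280 tests 135 were called with the preset value and 57 with an estimated correlation, all 57 among the 135. Fry called 181, 127 of them shared, and library totals 137, 129 shared, and none was called in the opposite direction.

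The replicate numbers do not pair the libraries. Over 36 pairs of groups the correlation of differences between replicates ran from -0.19 to 0.28 (median 0, 5 above 0.1). With a replicate block the counts were 942 for IFN in parental cells, 10154 for D2000 and 33 for the interaction, and no count moved by over 1.5 times. Depth limits genes with few counts: SAMD9 had 40 and 16 counts in untreated KRAB-D9 and 0 and 6 with doxycycline, and there a single library changed calls.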

Other observations

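All 3 tests in the last paragraph were chosen only after the result was seen. The cholesterol enzyme HMGCS1 and the haem enzyme ALAS2 went in opposite directions with the dCas9 fusions. In KRAB-D9 with doxycycline HMGCS1 rose from 262 to 417 CPM and ALAS2 from 245 to 398 CPM, while in D2000 they fell from 175 to 96.8 and from 116 to 40.4 CPM. Of the genes raised by doxycycline in KRAB-D9, 174 of 2654 were called higher in D6 and 138 lower, and 51% had the same sign. Of those lowered, 323 of 2815 were called lower and 164 higher, and 68% had the same sign.

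Mitochondrially encoded genes took 3.547 and 3.315% of the counts in parental cells with IFN, against 4.272 and 4.419% without. In KRAB-D9 they took 3.62 and 3.699% with both treatments against 4.786 and 4.752% with doxycycline. With IFN alone the libraries stood apart (4.12 and 3.403%, against 4.107 and 4.166% untreated).

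A set of 198 genes rose over 2-fold in both D2000 and D6, and 20 of them fell over 2-fold with doxycycline in KRAB-D9 (10.1%, against 1.22% of 21944 other genes, two-sided Fisher exact p = 1.53e-12, which restates what drew attention to the set). COL1A1, AIF1, CACNB1 and SFN, chosen after their values were seen, fell by 1.25, 1.29, 1.82 and 1.46. The hypothesis was that the fusion proteins act at such genes, so that falls would outnumber rises more than elsewhere. Falls and rises numbered 20 and 13, against 267 and 341 among other genes (two-sided Fisher exact p = 0.0722), which cannot tell. The set also rose over 2-fold more often than others (6.57 against 1.55%, Fisher exact p = 1.94e-05), so genes that vary widely under any exposure may account for part of the pattern.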
